A study of Arabidopsis thaliana with 26 samples.

How the data were processed

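Total RNA of Arabidopsis thaliana (accession Col-0) leaves was hybridised, biotin-labelled, to ATH1 arrays, a short-oligonucleotide platform in which each transcript is read by a probe set. The series held 26 arrays, all from the treatment that its title calls elevated CO2 with ambient light. Groups were taken from the labels: developing leaves at 2, 4, 12, 24, 48 and 96 h (4 arrays each) and mature leaves at 24 h (2 arrays). The labels number the replicates but do not say that they came from separate plants or batches, so p-values here measure the spread between these samples, which may be technical. Plants grew in compost at 20 °C and 50% humidity with 10 h of light per day, per the labels.

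The deposited values were linear signal intensities, made by the authors with MAS5 per the submitters' processing notes, which name no version. The deposited intensity columns each had a mean of 100 after trimming 2% of values at either end, which shows a global scaling; no background or detection call was used here. The table had 22810 probe sets, of which 64 were controls. No column of other samples was left unused.

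Values were transformed as log2(value + 16), so fold changes of dim probe sets are understated. A probe set was tested if it exceeded the 40th percentile of its array on at least 2 arrays, which left 16154. Array medians lay between 39.7 and 47.4, so no further scaling was applied. A linear model with 7 group means over all 26 arrays was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes(trend = TRUE), and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Contrasts between 6 pairs of groups and an F test over the 6 times in developing leaves were made. Several contrasts share the 2 h or the 24 h arrays, so overlaps between their calls were not computed. No arrays of untreated plants were used here, so no comparison tests the CO2 treatment itself. The 24, 48 and 96 h samples lie whole days apart. The 2, 4 and 12 h samples differ from these and from each other in time of day as well as in hours of treatment. The clock times are not given in the sources used here.

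Names came from a platform annotation, updated through gene identifiers with a gene table of assembly TAIR10.1; no coordinates were taken from it because the sources used here name no build. Of all probe sets, 13513 had 1 gene (13436 of them matched the gene table), 503 had several and 8794, controls included, were unlisted. Of the tested probe sets 8984 had 1 gene, 319 several and 6851 were unlisted; the last 2 kinds were counted but not named. Genes known to the table only by a locus code are given by that code.

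The gene lists, the contrasts, the rule for named genes and most alternatives were fixed before the data were examined. Of 461 genes on 30 lists fixed in that way, 56 had a tested probe set, so each such list is judged on a small part of its members. Another 13 lists were drawn up from gene names after the annotation had been read and before any test; they are called added lists. A gene on several probe sets counted through the brightest. The 25 lists with at least 3 tested genes were tested per contrast with limma's camera at a preset correlation of 0.01 (150 tests, adjusted together), again with the correlation estimated from the data, and with fry, which tests a list on its own. Of 38 calls, 2 held with the estimated correlation, both for the added list of cell division and chromatin genes. Fry gave 54 calls.

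Named genes were those with exactly 1 gene per probe set, an adjusted p under 0.05, a higher group mean above the median of all probe sets, and groups that do not overlap: the 5 highest and 5 lowest log2 changes for 12 h versus 2 h, 96 h versus 24 h and mature versus developing leaves, and the 3 highest and 3 lowest for the others. The 3 largest changes among the called members were added for the 5 lists (3 in the smaller contrasts) with most calls, among the fixed lists, and by the same rule among the added lists. For the F test the 5 genes with the widest range of group means among the 100 smallest p were taken. GI and the stomatal genes could be named anywhere. A few other list members are named too, chosen after their values were seen.

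The number of arrays limits the precision: the median 95% half-width of a log2 change was 0.27 between groups of 4 and 0.33 for mature leaves. On simulated data built from the spread of the 16154 probe sets, 48 h versus 24 h recovered 23 of 50 changes of 0.5 log2 and 49 of 50 changes of 1 log2, and mature versus developing leaves recovered 12 and 42 of 50. The simulated noise was independent between arrays, with the same spread in every group. The real developing 24 h and 48 h replicates had the lowest correlations (down to 0.956 and 0.9555), so on this account the recoveries may be too high. In each comparison 50 probe sets were changed by each of 0.5, 1, 2 and 4 log2, and 15954 stayed unchanged. The adjusted threshold loosens as more probe sets change. With 0 real calls at 48 h versus 24 h, recovery there may be lower still. With 8855 real calls in mature versus developing leaves, recovery there may be higher. Unchanged probe sets made up 3.37% of the simulated calls at 48 h versus 24 h and 7.78% in mature versus developing leaves, the latter above the threshold of 5%. Alternatives varied the pseudocount (1, 64), the filter (none, 60th percentile), quantile normalization, a replicate block, the groups in the fit, the variance trend, array weights and each array left out in turn. After the data were seen, 3 more were added: leaving out arrays with a high spike-in signal, leaving out arrays with a high 25S ribosomal RNA signal, and 3'/5' ratios as covariates.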

Results

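The data are signal intensities of 16154 tested probe sets on 26 arrays of Arabidopsis leaves from the elevated CO2, ambient light treatment. Developing leaves were sampled at 2, 4, 12, 24, 48 and 96 h (n = 4 arrays at each time) and mature leaves at 24 h (n = 2). The series title concerns systemic signalling of light and CO2 in this plant; the comparisons below follow developing leaves through the treatment and set mature against developing leaves. The labels do not say which leaves received the elevated CO2, so the developing leaves need not have been exposed themselves. Signals are given as mean ± SD in the deposited units, and changes as log2 values ± SE on the log2(value + 16) scale. Every array had a trimmed mean of 100, and medians ranged from 39.7 to 47.4. Replicate arrays correlated at r = 0.956 to 0.987 across probe sets, genes not being independent replicates, and no columns were identical.

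Quality measures set 2 arrays apart. The cre spike-in read 6451 on developing 24 h replicate 1 and 6745 on developing 48 h replicate 1, against a median of 2356 over all arrays. The 25S ribosomal RNA control read 4449 and 1571 on these arrays and 1536 on developing 96 h replicate 1, against a median of 67.8. Actin 3'/5' ratios lay between 1.37 and 2.33, and GAPDH ratios between 0.805 and 1.19.

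**Figure D1:**
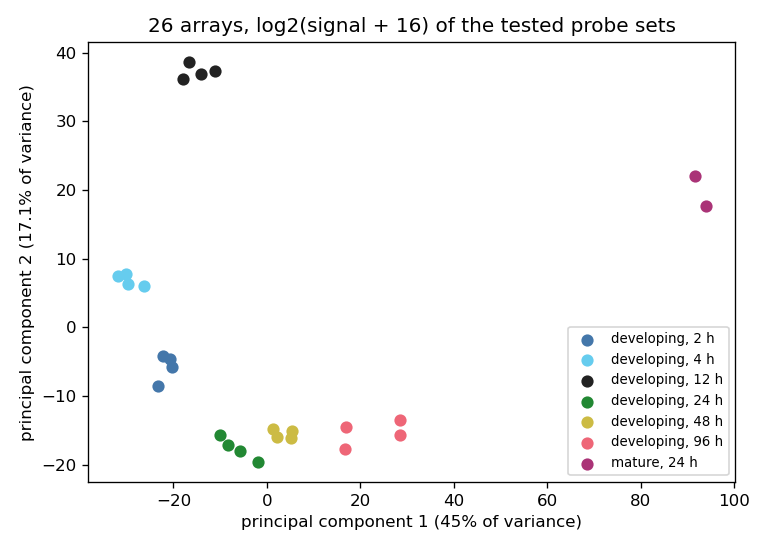
Principal components of the 26 arrays (1 point per array, coloured by group), with component 1 (45% of variance) on the x axis and component 2 (17.1%) on the y axis. The 12 h arrays stand apart on component 2, and the 24, 48 and 96 h arrays follow each other on component 1 towards the mature leaves.

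The first question was which genes changed over time in developing leaves. CCL, a gene named for its likeness to a circadian-regulated transcript, rose from 273 ± 21.8 at 2 h to 1015 ± 75.3 at 4 h and 1567 ± 95.9 at 12 h, and read 80.8 ± 12.5 at 24 h (adjusted p of the F test 6.5e-20). AT1G56300 peaked at 4 h with a mean of 342 (2 h: 57.2 ± 8.05) and read 10.8 ± 2.22 at 24 h and 10.2 ± 3.33 at 96 h. AT3G21670, AT5G12110 and AT1G66100 followed the opposite course: their 12 h means of 39.6 ± 14.8, 48.9 ± 5.70 and 88.7 ± 14.7 were the lowest of the 6 times, and their 24 h means were 516 ± 22.9, 731 ± 181 and 860 ± 236. GI, a component of the evening arm of the circadian clock, read 56.6 ± 5.52 at 2 h, 161 ± 13.5 at 4 h and 11.7 ± 5.64 at 12 h, then 46.8 ± 8.39, 41.7 ± 1.58 and 44.3 ± 5.11 at 24, 48 and 96 h (adjusted p of the F test 4.7e-14).

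In all, 8084 probe sets (50% of those tested) differed between times in the limma F test, 1749 of them with a range of at least 2-fold. Of the 8084, 2499 had their highest mean at 12 h and 2423 their lowest at 96 h, whereas the 48 h group held the highest mean for 443 and the lowest for 516. The 4 h group held the highest mean for 1759 of the 8084 and the lowest for 1860. Among the 1749, 96 h held the highest mean for 750 (4 h: 421, 12 h: 370) and 12 h the lowest for 598 (4 h: 417, 96 h: 411). Leaving out the 2 arrays with a high spike-in signal, chosen after seeing the data, gave 8501 probe sets, 7859 of them shared.

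**Figure D2:**
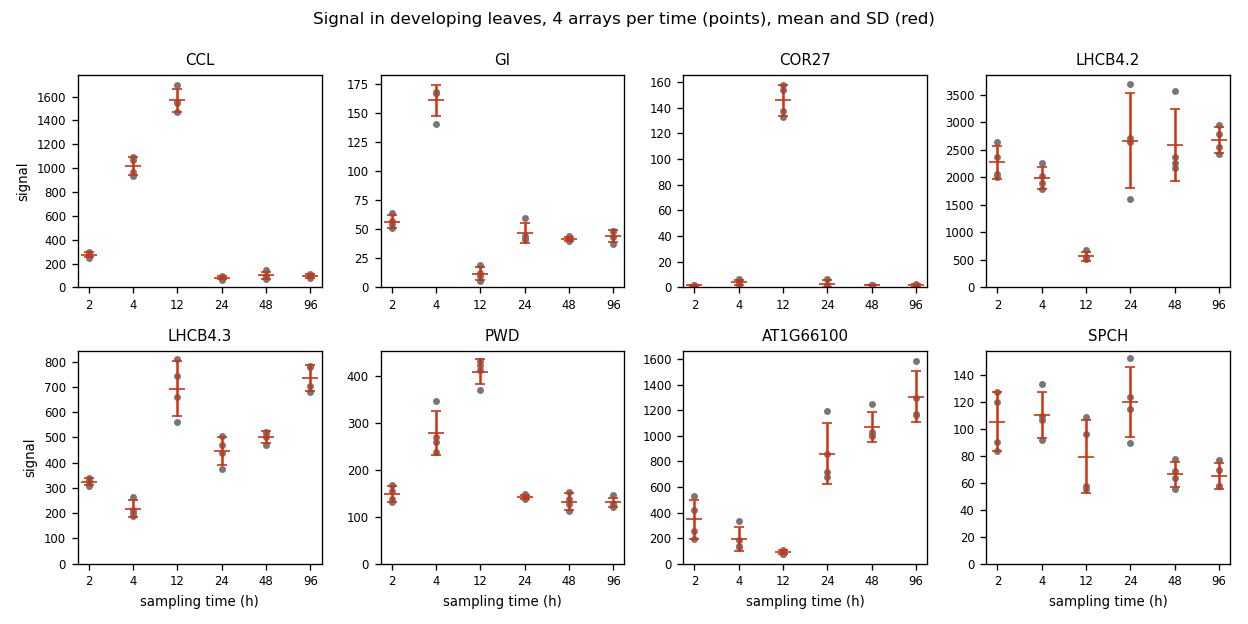
Signal (y axis, linear, from 0) of 8 named genes in developing leaves against sampling time in h (x axis, evenly spaced), with points for the 4 arrays and red bars for mean and SD. COR27 is near 0 at every time except 12 h, where its mean is 146.

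The comparison of 4 h versus 2 h in developing leaves covers the earliest step. GI rose by 1.28 ± 0.12 (adjusted p = 8.0e-08), CCL by 1.84 ± 0.14 and AT1G56300 by 2.29 ± 0.13, and AT4G32340 by 1.99 ± 0.15. Among genes of starch breakdown, PWD, a kinase that phosphorylates starch, rose from 148 ± 16.3 to 278 ± 47.7, and DPE1, a disproportionating enzyme acting on maltotriose, rose from 98.6 ± 8.88 to 177 ± 19.6. These were the 2 called members of 5 tested starch and sucrose genes (3 adjusted over the list alone; camera adjusted p = 0.031, and 0.24 with an estimated correlation). The list's median of -0.09 and its mean of 0.18 differ in sign. AUR2, a mitotic Aurora kinase, rose by 0.69 ± 0.10. With AUR1 it made 2 called of 3 tested cell division genes (3 adjusted over the list alone; camera adjusted p = 0.019, and 0.19 with an estimated correlation). Of 5 abscisic acid and cold response genes 1 was higher (2 adjusted over the list alone; camera adjusted p = 0.0014, and 0.17 with an estimated correlation). Among genes passing the naming rule, the largest falls were those of AT1G65490 (-1.02 ± 0.15), AT1G60590 (-0.86 ± 0.13) and AT5G48490 (-0.74 ± 0.12).

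The added list of 25 cell division and chromatin genes had 5 members higher and 1 lower (camera adjusted p = 0.0032, and 0.29 with an estimated correlation). TOPII, a topoisomerase, changed by 0.80 ± 0.19 and 3xHMG-box2, a chromatin protein, by 0.76 ± 0.17. Leaving out any of 3 and of 2 arrays, respectively, ended their calls, with adjusted p up to 0.11 and 0.059. AUR1, at 0.50 ± 0.13, lost its call without any of 6 of the 8 arrays. The tubulin TUB5 rose by 0.60 ± 0.12. Among beta-glucosidases, BGLU25 (0.48 ± 0.13) and BGLU44 (0.47 ± 0.12) passed the threshold, but leaving out any of 7 and of 6 arrays ended these calls. Of the stomatal genes, SPCH, which starts the stomatal lineage, differed by 0.06 ± 0.17, STOMAGEN, a secreted promoter of stomatal density, by -0.13 ± 0.11 and FMA (FAMA), which acts in guard cell formation, by -0.14 ± 0.12, none past the threshold. In total 220 probe sets were higher and 110 lower at 4 h. The 2 times differ in time of day as well as in hours of treatment.

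**Figure D3:**
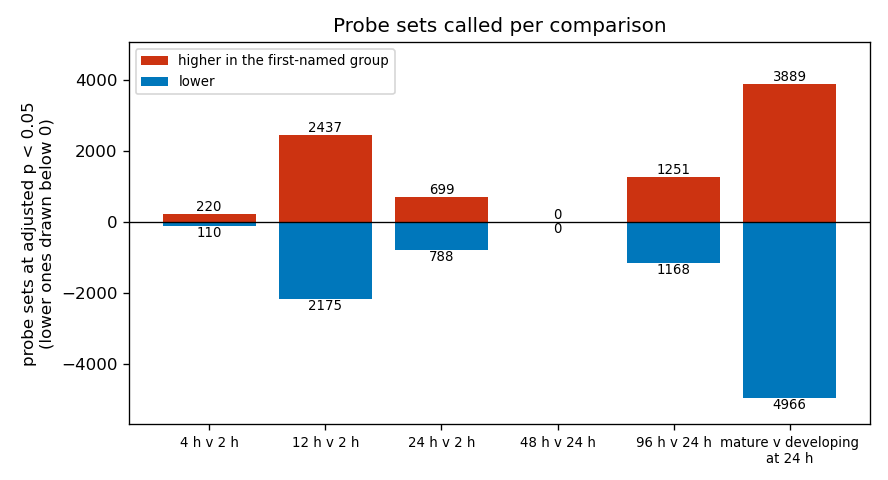
Number of probe sets past an adjusted p of 0.05 in each of 6 comparisons (x axis), with higher ones drawn upward and lower ones downward (y axis, probe sets). Counts run from 0 for 48 h versus 24 h to 3889 higher and 4966 lower in mature leaves.

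At 12 h versus 2 h in developing leaves, COR27 and AT1G13650 head the named genes. COR27, a cold-regulated gene, read 1.49 ± 0.541 at 2 h and 146 ± 12.1 at 12 h (adjusted p = 4.3e-17). CCL rose by 2.46 ± 0.14, AT3G60420 by 2.85 ± 0.35, AT4G32340 by 2.76 ± 0.15 and AT2G23910 by 2.63 ± 0.23, whereas GI fell to 11.7 ± 5.64. AT1G13650 (-3.03 ± 0.19), AT3G21670 (-2.81 ± 0.16), the cytochrome P450 CYP71B26 (-2.78 ± 0.16), AT3G28220 (-2.41 ± 0.19) and AT3G58660 (-2.12 ± 0.23) had the largest falls among genes passing the naming rule. LHCB4.2, an antenna protein of photosystem II, fell from 2271 ± 300 to 567 ± 84.5, and LHCB4.3, a related protein, rose from 325 ± 13.5 to 694 ± 108.

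Starch genes moved both ways at 12 h. PWD reached 409 ± 27.3 and DPE1 205 ± 25.7 (1.38 ± 0.10 and 0.94 ± 0.11), while SBE2.2, a branching enzyme, changed by -0.50 ± 0.18, a call lost without any of 6 of the 8 arrays. Of the list, 2 of 5 tested members were higher and 2 lower (5 adjusted over the list alone). Both tested sugar starvation genes rose (2 adjusted over the list alone): AKINBETA1, a subunit of the SnRK1 kinase, by 1.11 ± 0.14 and MCCA, which acts in leucine breakdown, by 0.72 ± 0.12. Photosystem I genes PSAN (-0.71 ± 0.13) and PSAE-1 (-0.63 ± 0.17) fell. In the cell division list, PRL (MCM7, a replication helicase subunit) fell by 0.86 ± 0.13 on the log2 scale, and AUR2 and AUR1 rose by 0.54 ± 0.10 and 0.45 ± 0.13. The added list of cytosolic ribosomal proteins had 64 of 106 genes lower and 0 higher, with a median of -0.33 (camera adjusted p = 8.1e-21, and 0.17 with an estimated correlation). Of these, AT3G57490 and AT5G39850 fell by 1.47 ± 0.21 and 1.44 ± 0.18, and AT3G06680 fell from 1113 ± 145 to 478 ± 93.5.

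Of the 25 cell division and chromatin genes, 11 were lower and 2 higher (camera adjusted p = 0.0068, and 0.3 with an estimated correlation), among them the histone genes HTB4 (-0.91 ± 0.10) and HTB1 (-0.90 ± 0.09) and the DNA polymerase subunit gene POLA3 (-0.89 ± 0.11). The 27 nuclear photosynthesis genes split into 6 higher and 6 lower (camera adjusted p = 0.73), the lower ones including CaS, a thylakoid calcium sensor (-0.92 ± 0.16). UDP-glycosyltransferases (5 higher, 3 lower of 27; camera adjusted p = 0.9) included UGT85A5 (1.08 ± 0.26), UGT85A4 (1.02 ± 0.17) and UGT74D1 (-0.94 ± 0.13). Cell wall loosening genes (2 higher, 5 lower of 25; camera adjusted p = 0.24) included the expansins EXPB1 (-0.89 ± 0.13), EXPA20 (0.69 ± 0.15) and EXPB3 (-0.65 ± 0.13). SPCH, at -0.37 ± 0.17, passed the threshold only in some settings, such as without developing 12 h replicate 3 (adjusted p = 0.021), and STOMAGEN and FMA did not pass it (-0.22 ± 0.11 and 0.05 ± 0.12). Altogether 2437 probe sets were higher and 2175 lower, 230 and 307 of them by at least 2-fold. These times, too, differ in time of day. With 10 h of light per day, both can lie in the light only at its very start and end. Whether leaves were in the light at sampling is not given in the sources used here.

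After the first day, at 24 h versus 2 h in developing leaves, AT5G12110 rose by 1.65 ± 0.14, HYH, a light-signalling transcription factor related to HY5, by 1.55 ± 0.14 (28.7 ± 3.42 to 114 ± 11.2) and TBL26 by 1.44 ± 0.19. AT4G30660 (-1.63 ± 0.13), CCL (-1.58 ± 0.14) and AT3G51660 (-1.50 ± 0.15) fell. HPR, the peroxisomal hydroxypyruvate reductase of photorespiration, rose by 0.81 ± 0.13 (adjusted p = 0.00013), the only called gene of 3 tested photorespiration genes (camera adjusted p = 0.017, and 0.3 with an estimated correlation; 2 adjusted over the list alone). PRK, the phosphoribulokinase of the Calvin cycle, rose by 0.60 ± 0.17, 1 called of 3 tested Calvin cycle genes (3 adjusted over the list alone; camera adjusted p = 0.022, and 0.37 with an estimated correlation). Of the 27 nuclear photosynthesis genes 4 were higher and 0 lower (camera adjusted p = 1.2e-05, and 0.37 with an estimated correlation).

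GI differed by -0.21 ± 0.12 and was not called. DPE1, the starch gene higher at 4 h and 12 h, fell by 0.70 ± 0.11 on the log2 scale at 24 h. The histone genes HTB11 (-0.74 ± 0.12) and HTB1 (-0.62 ± 0.09) fell, and 6 of 25 cell division and chromatin genes were lower with 0 higher (camera adjusted p = 0.00046, and 0.19 with an estimated correlation). Cytosolic ribosomal proteins had 8 of 106 lower (camera adjusted p = 0.027, and 0.7 with an estimated correlation), including AT3G57490 (-0.82 ± 0.21), AT2G40010 (-0.52 ± 0.12) and AT4G39200 (-0.78 ± 0.24), the last losing its call without any of 6 of 8 arrays. Other calls lay near the threshold. COR15A and COR15B, cold-induced chloroplast proteins (-0.83 ± 0.25 and -0.53 ± 0.15), and the sucrose phosphate synthase ATSPS4F (0.65 ± 0.19) lost theirs without any of 5 of 8 arrays, with changes then from -0.85 to -0.67, -0.49 to -0.44 and 0.45 to 0.65 and adjusted p of no more than 0.141, 0.102 and 0.139. So did the expansin-like EXLA2 (0.73 ± 0.19) and EXLB1 (0.56 ± 0.18) without any of 3 and 6, GH9B8, a glycosyl hydrolase (0.54 ± 0.14), and 3xHMG-box2 (-0.61 ± 0.17) without any of 2, and LHCB4.3 (0.44 ± 0.11) without developing 24 h replicate 4 (adjusted p = 0.055). SPCH, STOMAGEN and FMA differed by 0.16 ± 0.17, -0.08 ± 0.11 and -0.03 ± 0.12, none called. In total 699 probe sets were higher and 788 lower, and fitting only the 2 groups gave 931. The 24 h and 2 h samples differ in time of day as well as in hours of treatment.

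No probe set passed the threshold at 48 h versus 24 h in developing leaves, the first pair of times a whole day apart (0 of 16154 in limma; 1655 had an unadjusted p under 0.05). GI (41.7 ± 1.58 and 46.8 ± 8.39), STOMAGEN (307 ± 9.77 and 309 ± 26.2) and FMA (63.6 ± 10.2 and 60.6 ± 6.69) differed by no more than their spread. SPCH read 66.4 ± 9.22 at 48 h and 120 ± 25.9 at 24 h (-0.71 ± 0.17; adjusted p = 0.12). As a group, the cytosolic ribosomal proteins had a median of -0.20 (camera adjusted p = 2.8e-26, and 0.15 with an estimated correlation; 22 adjusted over the list alone), and the 5 flavonoid and anthocyanin genes a median of -0.59 (camera adjusted p = 0.00046, and 0.3 with an estimated correlation; 5 adjusted over the list alone). The count was 83 without developing 24 h replicate 1, 12 without developing 48 h replicate 1 and 2 without developing 48 h replicate 3; without both arrays with a high spike-in signal it was 15. With array weights it was 500, with the replicate block 19 and with a pseudocount of 64 it was 3. SPCH passed the threshold with the weights, with the block and without developing 24 h replicate 1 (adjusted p = 0.04).

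By 96 h versus 24 h in developing leaves, the largest rises among genes passing the naming rule were in AT1G13470 (2.33 ± 0.28), AT1G76960 (2.17 ± 0.22), AT3G60420 (2.14 ± 0.35), RING1, a ubiquitin ligase (67.4 ± 11.1 to 356 ± 97.6), and AT2G18690 (2.05 ± 0.25). GH3.3, an auxin-conjugating enzyme, fell from 57.7 ± 14.2 to 12.8 ± 5.13, and AUR2 from 95.5 ± 6.37 to 38.5 ± 5.48. AT1G66760 (-1.05 ± 0.25), GLC (-1.02 ± 0.13) and AT1G06100 (-1.01 ± 0.14) also fell. All 3 tested members of the cell division list were lower (3 adjusted over the list alone; camera adjusted p = 0.00046, and 0.074 with an estimated correlation): PRL fell by 0.61 ± 0.13 on the log2 scale, and AUR1 (-0.46 ± 0.13) lost its call without developing 96 h replicate 1 (adjusted p = 0.062). SPCH was lower at 96 h (65.3 ± 9.63; -0.73 ± 0.17; adjusted p = 0.0032), whereas STOMAGEN (-0.11 ± 0.11), FMA (-0.14 ± 0.12) and GI (-0.06 ± 0.12) were not called.

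Of the 25 cell division and chromatin genes 15 were lower and 0 higher, a shift that held with the estimated correlation (camera adjusted p = 9.2e-11, and 0.029 with an estimated correlation). TOPII (-0.83 ± 0.19) and the spindle checkpoint gene BUBR1 (-0.70 ± 0.14) were among them. Cytosolic ribosomal proteins were lower for 54 of 106 genes (camera adjusted p = 2e-20, and 0.17 with an estimated correlation), including AT4G30800 (-0.58 ± 0.10), AT2G19730 (-0.56 ± 0.12) and AT2G32060 (-0.56 ± 0.13). Of 27 UDP-glycosyltransferases 7 were higher (camera adjusted p = 0.0016, and 0.19 with an estimated correlation), led by UGT76B1 (1.70 ± 0.23), UGT87A2 (1.33 ± 0.16) and UGT72E1 (0.81 ± 0.20). UGT76B1 read 44.0 ± 26.7 at 96 h and 1.19 ± 1.08 at 24 h, and UGT72E1 25.1 ± 5.79 and 7.63 ± 4.82. Their 24 h means, and nearly the 96 h mean of UGT72E1, lay below the lowest 40th percentile of any array, 24.3. Both tested glucosinolate genes were higher, BCAT4, an aminotransferase of methionine chain elongation, from 58.5 ± 7.77 to 145 ± 26.2, and UGT74B1 by 0.56 ± 0.18 (2 adjusted over the list alone), the latter lost without any of 5 of 8 arrays.

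Cell wall loosening genes were higher for 5 and lower for 1 of 25 (camera adjusted p = 0.18), with the expansins EXPA8 (1.14 ± 0.17) and EXPB1 (0.76 ± 0.13) and the glucanase GH9C2 (0.73 ± 0.09). ATSPS4F (1.06 ± 0.19) and APL3, a subunit of ADP-glucose pyrophosphorylase (0.52 ± 0.12), rose, and the phloem marker SWEET11, a sucrose exporter, rose by 0.55 ± 0.13, and the trichome marker TRY by 0.46 ± 0.13. COR47, a dehydrin, fell by 0.61 ± 0.14 on the log2 scale. COR15A (0.84 ± 0.25) was higher, but lost its call without developing 96 h replicate 1 (adjusted p = 0.1) or developing 24 h replicate 3 (0.094). Its change was then 0.69 to 0.71. LHCB4.3 (0.70 ± 0.11) and NdhN, a subunit of the chloroplast NDH complex (0.53 ± 0.11), rose, while NdhL (0.44 ± 0.13) lost its call without any of 5 arrays. In total 1251 probe sets were higher and 1168 lower, 165 and 8 of them by at least 2-fold. Fitting only the 2 groups gave 1565, leaving out developing 96 h replicate 1 gave 1600, and leaving out developing 96 h replicate 4 gave 1623.

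**Figure D4:**
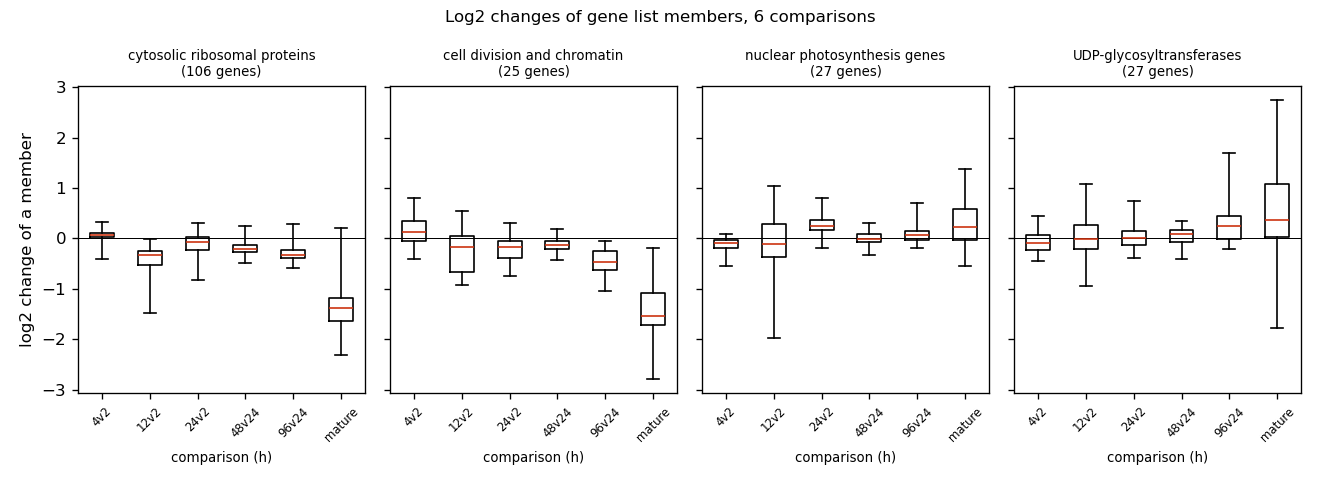
Log2 changes (y axis) of the members of 4 added gene lists in 6 comparisons (x axis, in h; mature is mature versus developing leaves at 24 h), as boxes of the quartiles with the median in red and whiskers to the lowest and highest member. The ribosomal protein median is -0.33 at both 12 h versus 2 h and 96 h versus 24 h in rounded values (-0.332 and -0.325) and -1.38 in mature leaves.

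Mature versus developing leaves at 24 h gave the widest contrast. AT1G76960 (494 ± 69.0 against 1.64 ± 0.773), PPDK, a pyruvate orthophosphate dikinase (732 ± 112 against 12.8 ± 4.53), BCAT4 (1653 ± 52.6 against 58.5 ± 7.77), AT1G64370 (802 ± 171 against 21.2 ± 6.70) and AT3G28540 (424 ± 99.5 against 7.45 ± 4.89) had the largest rises among genes passing the naming rule. AT2G33850 read 1.02 ± 0.466 in mature and 1687 ± 146 in developing leaves (-6.64 ± 0.14; adjusted p = 4.4e-23), followed by AT4G29030 (-4.85 ± 0.30), AT1G62500 (-4.49 ± 0.36), LCR69, a defensin-like protein (48.4 ± 9.25 against 1011 ± 71.7), and AT4G29020 (-3.96 ± 0.14).

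All 3 tested stomatal genes were lower in mature leaves: SPCH read 3.67 ± 1.03 against 120 ± 25.9, STOMAGEN 66.3 ± 6.88 against 309 ± 26.2, and FMA changed by -0.56 ± 0.15 (3 adjusted over the list alone; camera adjusted p = 0.024, and 0.17 with an estimated correlation). The division genes PRL (-2.25 ± 0.16), AUR2 (-1.77 ± 0.12) and AUR1 (-1.65 ± 0.15) were all lower (3 adjusted over the list alone; camera adjusted p = 0.0067, and 0.17 with an estimated correlation). In the added list, 24 of the 25 cell division and chromatin genes were lower with 0 higher (camera adjusted p = 1.6e-11, and 0.029 with an estimated correlation), including TOPII, 3xHMG-box2 and HTB1 at -2.79 ± 0.23, -2.66 ± 0.20 and -2.31 ± 0.11. Of 106 cytosolic ribosomal protein genes 105 were lower (camera adjusted p = 2.9e-33, and 0.074 with an estimated correlation), with AT3G10610, AT3G06680 and AT3G52580 at -2.31 ± 0.13, -2.24 ± 0.16 and -2.14 ± 0.11. The leaf polarity genes YAB3 (-1.09 ± 0.13) and PHV (-0.71 ± 0.14) were lower, but the list of 3 leaf growth genes did not pass (camera adjusted p = 0.17; 3 adjusted over the list alone). YAB5 (-0.40 ± 0.17) lost its call without any of 3 arrays and after quantile normalization.

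The abscisic acid and cold response genes split in mature leaves, with 3 higher and 2 lower of 5 (5 adjusted over the list alone; camera adjusted p = 0.18). STZ (ZAT10), a zinc finger protein of cold and salt responses, read 466 ± 22.1 against 33.9 ± 12.0, and COR15A 484 ± 50.6 against 46.1 ± 11.9; COR15B (0.63 ± 0.19) lost its call without mature 24 h replicate 1, and COR47 was lower (-0.43 ± 0.18). Of 3 jasmonate and wounding genes 1 was higher and 1 lower (2 adjusted over the list alone; camera adjusted p = 0.81). Both tested salicylate defence genes, WRKY53 and SAG101, were higher (2 adjusted over the list alone). Among UDP-glycosyltransferases 13 were higher and 4 lower of 27 (camera adjusted p = 0.018, and 0.3 with an estimated correlation), with UGT76B1, UGT87A2 and UGT72E1 at 2.74 ± 0.28, 2.50 ± 0.20 and 2.36 ± 0.24. Of the flavonoid and anthocyanin genes 4 of 5 were lower (5 adjusted over the list alone; camera adjusted p = 0.19): DFR changed by -0.98 ± 0.26, UF3GT by -1.35 ± 0.42 and AT5MAT by -0.99 ± 0.33, the last 2 losing their calls without mature 24 h replicate 1 and mature 24 h replicate 2, respectively.

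Both tested cell expansion genes were called (2 adjusted over the list alone), EXPA8 higher and EXPA4 lower (-0.74 ± 0.16). Cell wall loosening genes split, with XTH16 at -2.91 ± 0.15, EXPA8 at 2.89 ± 0.21 and EXLA1 at 1.98 ± 0.22 (2 higher and 12 lower of 25). Of 69 plastid-encoded genes 12 were higher and 6 lower (13 adjusted over the list alone; camera adjusted p = 0.32), with psbE at 1.72 ± 0.23, rpl14 at -1.52 ± 0.30 and ycf3 at -1.52 ± 0.41, the last lost without mature 24 h replicate 1. GI did not differ (50.6 ± 10.8 against 46.8 ± 8.39). Single markers of cell types differed too: SWEET11 (phloem) read 626 ± 21.3 against 109 ± 22.0, AT1G22690 (guard cells) 235 ± 5.45 against 102 ± 11.6 while the other tested guard cell marker, FMA, was lower, TRY (trichomes) 127 ± 30.2 against 58.9 ± 7.37, and PYK10 (root) 7.53 ± 4.17 against 18.1 ± 3.61. Both PYK10 means lay below the lowest 40th percentile of any array, 24.3, and so near the background. Altogether 3889 probe sets were higher and 4966 lower in mature leaves, 54.8% of those tested. The median change of all tested probe sets was -0.10, and -0.06 after quantile normalization, and mature leaves had only 2 arrays. The SE and p-values of this comparison rest on a spread shared by all groups. They say little about the spread between mature leaves.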

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

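In 300 groups of 4 arrays examined, 20 had an array far from the other 3 by Dixon's test of gap over range, where chance gives 15. Single entries may thus be chance alone. Groups share arrays, so the 300 are not independent. Most entries fall on replicate 1 arrays, chiefly developing 24 h and 48 h replicate 1, which also had high spike-in signals. The test was set in advance; the genes examined are the named ones.

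Among array measures, the 25S ribosomal RNA control read 4449 on developing 24 h replicate 1 (others 16.8 to 74.2), 1571 on developing 48 h replicate 1 (others 38.9 to 65) and 138 on developing 2 h replicate 1 (others 35.4 to 50.8). On developing 48 h replicate 1 the cre spike-in read 6745 (others 1718 to 2358) and the bioC spike-in 458 (others 117 to 173). The GAPDH 3'/5' ratio was 0.805 on developing 12 h replicate 4 (others 1.08 to 1.1).

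Among genes at 24 h, developing replicate 1 stood apart for GI (59.3), NdhN (367), TOPII (76.3) and UGT76B1 (2.8), and developing replicate 2 for AT3G10610 (976) and AUR1 (108, others 172 to 183). At 2 h, COR15B read 74.1 on replicate 1 and PSAE-1 read 2350 on replicate 4. At 4 h, GI read 140 on replicate 3 (others 167 and 168). At 12 h, AT1G13650 read 11.8 on replicate 2 and UGT85A4 read 66.9 on replicate 4. At 48 h, AT1G66100 read 1250 on replicate 1. At 96 h, AT1G06100 read 141 on replicate 2 and PRL read 125 on replicate 1 (others 176 to 179).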

How the results depend on the processing

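Of 169 results for named genes, 151 were called and 142 were alike in every planned setting; none reversed in any setting, 14 lost their call in a planned setting other than leaving out an array, and 24 lost it when an array was left out. In the settings added later, 9 lost it without the high 25S arrays, 6 without the high spike-in arrays and 5 with 3'/5' ratios as covariates.

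The counts for the F test, 12 h versus 2 h and mature versus developing leaves stayed within 1.5 times the main count throughout. At 4 h versus 2 h, array weights gave 565 in place of 330. At 24 h versus 2 h, the 2 groups alone gave 931 in place of 1487, and at 96 h versus 24 h 1565 in place of 2419; leaving out arrays gave 1600 to 2486 at 96 h. Without the arrays with a high spike-in signal, 1114 of the 1487 calls and 2138 of the 2419 calls stayed. Without the arrays with a high 25S signal, 1126 and 1657 stayed. At 48 h versus 24 h, the count of 0 became 3 with a pseudocount of 64, 19 with the replicate block, 500 with array weights, 15 without the arrays with a high spike-in signal, 25 without those with a high 25S signal and 0 to 83 without single arrays. The cause of these differences was not tested. Fits with fewer arrays have fewer degrees of freedom, but this did not lower every count. The 2 groups alone gave 4719 in place of 4612 at 12 h versus 2 h, and 288 in place of 330 at 4 h versus 2 h.

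No comparison had every same-numbered pair of arrays deviating together at r above 0.1, the bar used here for pairing (pairs from -0.104 to 0.517). All pairs at 4 h and 12 h versus 2 h were above 0, and 7 of 8 arrays at 4 h versus 2 h, but 3 of 8 at 48 h versus 24 h, correlated best with their own number, so some sharing by number is open. With the replicate block the counts were 372, 4834, 1656, 19, 2689 and 8940 for the 6 comparisons in order and 8427 for the F test. For gene lists, 36 of 38 calls were lost with an estimated correlation, 3 with quantile normalization (which added 10) and 3 with the block. Signal near the background limits dim genes, whose changes the pseudocount understates.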

Other observations

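The tests of a lasting change, of simulated recovery and of leaf ageing were chosen only after their results were seen. Those with 3'/5' ratios or with arrays left out were added after the data were seen, their outcomes being set before they were run. Autophagy genes of the ATG8 family, whose products coat autophagosomes, were higher at 12 h than at 2 h for 6 of 9 members (ATG8E 1.32 ± 0.23, ATG8F 0.83 ± 0.13; camera adjusted p = 0.012, and 0.37 with an estimated correlation) and in mature leaves for 6 of 9 (APG8H 1.70 ± 0.12; 0.018 and 0.37). Of 9 plastid ribosomal proteins 8 were lower in mature leaves (camera adjusted p = 0.0021, and 0.33 with an estimated correlation), as were 6 of 10 chlorophyll and haem synthesis genes (0.074 and 0.37). PORB, a protochlorophyllide reductase, changed by 0.41 ± 0.14 at 12 h and by -0.62 ± 0.14 at 24 h, both against 2 h. In mature leaves 11 of 15 wounding, touch and early stress genes were higher and 1 lower (camera adjusted p = 0.00024, and 0.24 with an estimated correlation), with ORA47 at 3.23 ± 0.24, OPCL1 at 1.86 ± 0.22 and PUB23 at -0.95 ± 0.19. WRKY53 (1.72 ± 0.19) and SAG29 (2.35 ± 0.19), which rise in ageing leaves, were also higher. These members were chosen after their values were seen.

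Splitting these arrays at random did not give 5 of the counts. As replicates need not be separate plants, this does not exclude chance differences between plants. Of 35 splits of the 8 arrays, 1 (the real one) gave as many calls at 4 h versus 2 h (330, highest other 9), 12 h versus 2 h (4612, 6), 24 h versus 2 h (1487, 2) and 96 h versus 24 h (2419, 130), and 1 of 100 drawn orders of the 24 arrays did for the F test (8084, 698). At 48 h versus 24 h all 35 splits gave at least the 0 calls found, as any split must, so this tests nothing. Another split gave 430, a sign of some structure among these arrays whose source was not tested. The replicate 1 arrays of 24 h and 48 h, those with a high spike-in signal, deviated together at r = 0.517. The other same-numbered pairs lay between -0.0158 and 0.223.

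The large difference between 12 h and 2 h was not explained by the 3'/5' ratios or by array distribution: 4513 probe sets passed with 3'/5' ratios as covariates and 4624 after quantile normalization, against 4612. The mean ratios at 12 h and 2 h were 1.705 and 1.85 for actin and 1.019 and 1.044 for GAPDH. With so small a gap the covariates could hardly alter the count, so RNA quality in general is not excluded. Of the 537 probe sets changed at least 2-fold at 12 h, a median of 12.8% of the log2 change remained at 24 h. For these probe sets as a set, this argues against a change lasting from 12 h on. They were picked by their change at 12 h, which lowers the share, while the shared 2 h arrays raise it. A lasting change in some of them stays possible. A daily rhythm, light against dark at sampling and a passing response to the treatment all stay open. No untreated arrays were used here.

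For the count of 0 at 48 h versus 24 h, leaving out the pair of arrays with a high spike-in signal gave 15 calls and leaving out each other same-numbered pair gave 0, which lies between the outcomes set beforehand for this explanation. Small changes may also have gone uncalled, as 46% of simulated changes of 0.5 log2 were recovered. That share may be too high for these arrays, also because the simulation held changes of up to 4 log2 that loosen the adjusted threshold. The values do not show a lack of change: component 1 ran from -10.0 to -1.83 on the 24 h arrays and from 1.22 to 5.34 on the 48 h arrays. Why no probe set passed stays open.

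Developing leaves at 96 h lay nearer to mature leaves. With no shared arrays, the change from 48 h to 96 h correlated with mature minus developing leaves at r = 0.543 across probe sets. This was above the other 34 splits, the highest of which reached 0.527. A correlation does not shrink with the size of a difference, so splits that keep most of the real grouping can score nearly as high. The rank therefore adds little. From 48 h to 96 h the median change was 0.24 for probe sets at least 2-fold higher in mature leaves (1562) and -0.17 for those at least 2-fold lower (1468), against -0.04 for all. A trend with signal level (r = 0.566 once removed) and the arrays with a high 25S signal (r = 0.527 without them) do not account for it. Not all genes followed: SAG29 was not called at 96 h versus 24 h (-0.21 ± 0.16), and of 25 cell wall loosening genes 5 were higher and 1 lower at 96 h versus 24 h, against 2 higher and 12 lower in mature leaves. As a hypothesis, the correlation is consistent with leaf ageing between 48 h and 96 h; a slow effect of the treatment stays untested.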
